A study of Mus musculus with 12 samples.

How the data were processed

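Gene expression was measured by RNA sequencing of total RNA (column extraction, with enzymatic removal of ribosomal RNA) in stromal cells of the mouse gut, sorted as EPCAM negative and CD45 negative and then as negative or positive for a GFP reporter of Rspo3. The animals were 8 to 12 weeks old on a C57Bl6 background. The 12 libraries form 4 groups of 3, GFP-negative and GFP-positive cells of the small intestine and GFP-negative and GFP-positive cells of the colon. Samples sorted on CD31, which the design text of the series also names, are not analysed here. The labels do not say that the replicates came from separate animals, so the p-values may measure technical spread as well as differences between animals.

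Per the submitters' processing notes the upstream tools were Salmon 1.1.0 and R 3.6.1 with the mm10 build. The notes do not state the annotation, any filter or any rounding. The deposited estimated counts (expected counts per gene) are whole numbers in 100% of the cells, and since Salmon estimates fractional counts they were taken as rounded estimates. The second deposited table is on the log2 scale, as log2(TPM + 1), where TPM is transcript abundance scaled to a fixed total per library. Both tables hold 32052 genes, each with a total of at least 1 over the 12 libraries. Of these, 31974 identifiers were given symbols and positions from GENCODE M21 (GRCm38, the same assembly as mm10) and 78 had none. There were 38 symbols carried by more than 1 identifier, and 18027 genes were protein coding.

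The libraries held between 6489835 and 12286054 counts. In the small intestine these were 7966684, 9708867 and 6489835 for GFP-negative replicates 1 to 3 and 12286054, 11435834 and 9018126 for GFP-positive replicates 1 to 3. In the colon they were 6562662, 8003415 and 7299851 for GFP-negative and 9120583, 7735300 and 8746724 for GFP-positive replicates. Between 18933 and 23338 genes had a count in each library. The genes mt-Rnr1 and mt-Rnr2 took 5.35% to 12.7% of counts, mitochondrial mRNAs 0.583% to 1.44%, and the rRNA-like genes Gm42418 and Gm26917 together 2.02% to 3.72%. Small noncoding genes took 3.74% to 7.50% of counts but 89.6% to 93.5% of TPM, because TPM divides by length, so counts were used for the main tests and the TPM scale as an alternative.

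Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3. One model with a mean per group was fitted to all 12 libraries, with TMM factors and filterByExpr at a minimum count of 10, which left 16757 genes. Benjamini-Hochberg adjusted p under 0.05 over these genes was the threshold for a call, and only called genes are said to have risen or fallen. Fold changes are log2 values with the standard error (SE) taken from the size and the F statistic. CPM are counts scaled to a common library size with the TMM factors, and group values are means with SD over 3 libraries. A gene without any count in one group has no finite fold change, so its bound was computed against a floor of 3 counts over the group, which covers counting error only. The 5 comparisons were GFP-positive minus GFP-negative in the small intestine and in the colon, the difference of these effects (colon minus small intestine, an interaction term), and colon minus small intestine within GFP-positive and within GFP-negative cells.

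Before the data were examined, 41 gene lists were fixed from textbook knowledge of gut stroma, of which 40 had at least 3 tested members. They cover niche signals (R-spondins, Wnt ligands and antagonists, BMP ligands and antagonists, EGF family, other growth factors), Wnt and hedgehog targets, and markers of stromal and other cell types. They also cover collagens, complement, stromal chemokines and cytokines, interferon response and antigen presentation, retinoid and prostaglandin genes, regional genes (anterior and posterior Hox genes, gut mesenchyme transcription factors, small intestinal and colonic epithelium), immediate early and stress genes, cell cycle, nuclear RNAs and mitochondrial mRNAs. The erythroid list had too few tested members. Rspo4, Wnt3, Dkk1, Dkk4, Ptgds, Hoxc12, Hoxc13 and mt-Co2 were listed but are not in the tables. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, whose directional p asks whether a list's genes move, on balance, one way. Within each list, calls over all genes and calls adjusted over the list alone were counted.

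Named genes followed a rule set before the data were examined. It takes Rspo3 and the niche list members whether called or not. It takes the 10 genes with the largest fold change in each direction among called genes whose groups do not overlap (not asked for the interaction), with a mean log2 CPM of at least 4 and an established symbol. It also takes up to 4 called members of each list with the smallest adjusted p, or where none was called up to 3 with the highest mean. The text leaves out some of these and names any gene outside the rule as chosen after its values were seen. The comparisons, tests, lists and most alternatives were likewise chosen before the data were examined.

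The alternatives were RLE factors, library sizes without factors, no filter, a stricter filter on low counts, the deposited log2 scale tested with limma, DESeq2 1.42.0, limma-voom, a fit to only the libraries compared, a replicate block, and leaving out each library in turn. Another asked for an absolute log2 fold change of at least 1 besides the adjusted p. Added after the data were seen were log2 of TPM plus 0.1, protein-coding genes only, and leaving out both small intestinal libraries of replicate 3. The labels do not state a pairing, but the column labels carry an identifier shared by all 4 libraries of replicate 3 and another shared by both sorts of colonic replicate 2, whose meaning is not given. The residuals of small intestinal libraries with the same replicate number correlated at 0.323, 0.179 and 0.166, each above the correlations with the other numbers. The numbers may thus pair the small intestinal sorts. With 3 libraries per sort few matchings are possible, so these values do not settle it. In the colon these values were 0.009, 0.047 and 0.09. Between tissues they were 0.02, 0.05 and 0.054 in GFP-positive cells and 0.098, 0.028 and 0.223 in GFP-negative cells, the highest for replicate 3. Whether libraries of a number came from 1 animal is left open, and the block is an alternative in every comparison.

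The procedure was tested on simulated data drawn from the libraries' own sizes and spreads, with 200 changed genes per comparison. Of genes changed 4-fold, 59.4% were recovered in the small intestine, 68.9% in the colon, 32.3% for the interaction, 62.3% between tissues in GFP-positive and 54.0% in GFP-negative cells. Of genes changed 2-fold, between 0 and 16.4% were recovered, so most 2-fold changes are missed at this number of libraries. Between 1% and 8.16% of the calls were of unchanged genes. The simulation gave every group the same spread per gene, which the real groups did not have. Log2 CPM of replicates correlated at 0.834 to 0.894 in small intestinal GFP-negative libraries and at 0.938 to 0.948 in colonic GFP-negative ones. The simulated rates may therefore not hold for single comparisons of the real data. Within each group no library was a copy of another. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.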

Results

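Rspo3 encodes R-spondin 3, a secreted amplifier of Wnt signalling (ENSMUSG00000019880, chromosome 10, 29452416 to 29535867 on the minus strand of GRCm38). It separated the GFP-positive from the GFP-negative libraries in both tissues. In the small intestine it measured 8.78, 13.7 and 4.5 CPM in GFP-negative replicates 1 to 3 and 196, 191 and 192 CPM in GFP-positive replicates 1 to 3. In the colon the values were 2.49, 6.51 and 2.28 CPM in GFP-negative and 161, 117 and 119 CPM in GFP-positive replicates. The log2 difference was 4.41 ± 0.42 (SE, n = 3 per group, adjusted p = 1.74e-04) in the small intestine and 5.11 ± 0.45 (adjusted p = 6.42e-05) in the colon. Because the cells were sorted on a reporter of this gene, the difference checks the labels and is no finding of its own.

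In the small intestine, GFP-positive cells carried more of the R-spondins and of most Wnt ligands that were called, together with the BMP antagonist Grem1. Grem1 (gremlin 1, chromosome 2, 113746164 to 113758646) rose by 4.36 ± 0.42 on the log2 scale (adjusted p = 1.46e-04), from 50.4 ± 23.3 to 1030 ± 498 CPM (mean ± SD, n = 3). Rspo1 rose by 2.71 ± 0.49 (adjusted p = 0.00385) and Rspo2 by 3.08 ± 0.60 (adjusted p = 0.00623), so all 3 R-spondins tested were higher. Wnt2, a canonical Wnt ligand (chromosome 6, 17988940 to 18030585), rose by 5.65 ± 0.65 (adjusted p = 3.56e-04), from 0.808 to 41.9 ± 35.1 CPM, and Wnt9a rose from 6.01 to 20.2 CPM (adjusted p = 0.0145). Wnt2b rose from 121 to 340 CPM (adjusted p = 0.0261), but 4 of the 6 fits without a library ended that call, the highest adjusted p being 0.09 without GFP-positive replicate 3. Wnt4 fell by 2.17 ± 0.34 (adjusted p = 0.00166), while the non-canonical ligands Wnt5a and Wnt5b were not called at 0.17 and 0.21. Of 10 Wnt ligands tested, 5 rose and 1 fell over all genes, and 6 rose and 2 fell adjusted over the list alone. Besides Wnt2b, Wnt9b and Wnt10b lost their calls in 3 and 4 of the 6 fits without a library, with 0.108 without GFP-positive replicate 2 and 0.12 without GFP-negative replicate 1. The Wnt ligand list was called (camera adjusted p = 0.00954), with adjusted p = 0.148 with an estimated correlation. The R-spondin list, which holds the sorted gene, gave an adjusted p = 9.68e-05, and adjusted p = 0.0914 with an estimated correlation.

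Signals that oppose or complement Wnt moved in both directions in small intestinal GFP-positive cells. Sostdc1, an antagonist of both Wnt and BMP, fell by 7.95 ± 0.94 (adjusted p = 4.13e-04), from 11.9 to 0.0394 CPM. The BMP antagonist list, with 2 of 12 members higher and 1 lower, was not called (adjusted p = 0.0592), nor was the Wnt antagonist list (adjusted p = 0.491). None of the 8 BMP ligands was called, with Bmp2 at 0.20, Bmp4 at -0.41, Bmp5 at -1.35 and Bmp7 at -1.10 (list adjusted p = 0.224). Among other growth factors 5 of 19 rose (3 without GFP-negative replicate 3) and 2 fell. Fgf7, a keratinocyte growth factor, rose by 2.35 ± 0.32 (adjusted p = 7.05e-04), from 6.11 to 31.2 CPM. The lymphangiogenic factor Vegfd rose by 2.17 ± 0.35 (adjusted p = 0.00183) and Gas6, a ligand of TAM receptor kinases, rose from 90.3 to 259 CPM (adjusted p = 0.00746). Fgf10 fell by 2.69 ± 0.52 (adjusted p = 0.00555), and Kitl, the ligand of the Kit receptor, fell from 125 to 28.7 CPM (adjusted p = 0.00346). The EGF family ligand Areg (amphiregulin) fell by 3.64 ± 0.69 (adjusted p = 0.00627). The EGF family list was called as lower (adjusted p = 0.0113), and adjusted p = 0.4 with an estimated correlation, though Areg was its only called member. Wnt targets, with 2 of 10 lower and 4 adjusted over the list alone (list adjusted p = 0.224), and hedgehog targets, with none of 8 called (list adjusted p = 0.962), were not called as lists against other genes, though fry called the Wnt targets as lower (adjusted p = 0.00117).

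**Figure D1:**
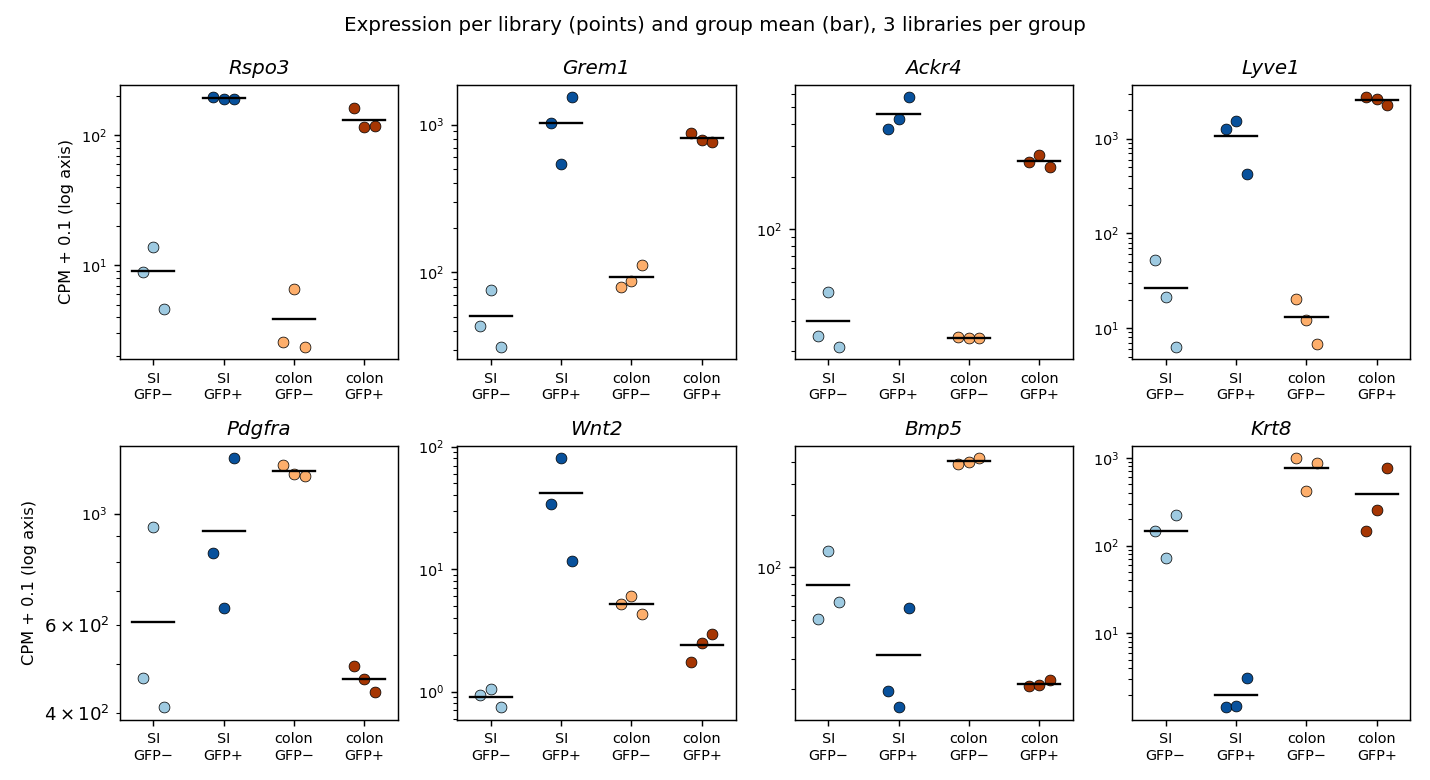
CPM plus 0.1 on a log axis for 8 genes in the 12 libraries, with points for libraries and bars for group means (n = 3; SI is small intestine). Rspo3, Grem1, Ackr4 and Lyve1 are higher in all GFP-positive than in all GFP-negative libraries of both tissues.

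The small intestinal GFP-positive libraries were rich in markers of lymphatic endothelium and of fibroblasts. Lyve1, a hyaluronan receptor of lymphatic vessels, rose by 5.34 ± 0.78 (adjusted p = 0.00168), from 26.5 to 1080 CPM, and the lymphatic genes Mmrn1 and Reln rose by 5.35 ± 0.82 and 4.51 ± 0.56. Ccl21a, a chemokine of lymphatic endothelium whose reads are hard to tell from those of its paralogs, rose by 6.34 ± 0.86. Of 11 lymphatic markers 7 rose and none fell over all genes (9 rose adjusted over the list alone; list adjusted p = 9.95e-09, and adjusted p = 0.148 with an estimated correlation). Alox12e, a lipoxygenase gene, Slc45a3 and Ackr2, a scavenging chemokine receptor, were among the genes that rose most, by 7.13 ± 1.07, 5.19 ± 0.64 and 5.15 ± 0.69. Trophocyte markers rose in 8 of 14 cases and fell in 2 (list adjusted p = 1.14e-05, and adjusted p = 0.204 with an estimated correlation). Ackr4, an atypical chemokine receptor and the marker of this submucosal fibroblast, rose by 3.94 ± 0.28 (adjusted p = 2.36e-05), from 29.8 ± 12 to 458 ± 100 CPM. Of 13 general fibroblast markers 8 rose and none fell, including the proteoglycans Lum (169 to 1120 CPM, adjusted p = 6.69e-04) and Dcn (1750 to 8280 CPM, adjusted p = 0.00177). That list gave an adjusted p = 5.06e-08, and adjusted p = 0.4 with an estimated correlation.

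Most markers of blood endothelium, glia, pericytes and smooth muscle fell in small intestinal GFP-positive cells. The blood endothelial genes Flt1, a VEGF receptor, and Plvap, a component of fenestrated endothelium, fell by 6.94 ± 0.78 and 4.99 ± 0.79, from 379 to 3.11 and from 638 to 20 CPM. Of 13 blood endothelial markers 9 fell and 1 rose (list adjusted p = 9.64e-07, and adjusted p = 0.353 with an estimated correlation), whereas of 12 markers common to all endothelium 1 fell (list adjusted p = 0.273). The glial filament gene Gfap fell by 5.91 ± 0.79, and 9 of 11 enteric glia markers fell with 1 higher (list adjusted p = 3.08e-10, and adjusted p = 0.0914 with an estimated correlation). Pericyte markers fell in 6 of 10 cases, with Cspg4 from 196 to 19 CPM and Notch3 lower by a log2 of -6.82 ± 0.78 (list adjusted p = 2.99e-04, and adjusted p = 0.44 with an estimated correlation). Smooth muscle myosin Myh11 fell from 1570 to 418 CPM, and 7 of 11 smooth muscle markers fell, or 3 without GFP-positive replicate 1 (list adjusted p = 0.00954, and adjusted p = 0.602 with an estimated correlation). The smooth muscle list lost its call without GFP-negative replicate 2 (adjusted p = 0.202), as did the telocyte list, in which 1 of 14 rose and 1 fell (adjusted p = 0.0115, and 0.111 without that library). The telocyte list had adjusted p = 0.487 with an estimated correlation. Enteric neuron markers, none of 8 called, gave an adjusted p = 0.00538 that rose to 0.253 without GFP-positive replicate 2, and adjusted p = 0.509 with an estimated correlation. The lists for interstitial cells of Cajal (adjusted p = 0.194) and mesothelium (adjusted p = 0.902, median -1.41 and mean 0.02) were not called.

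Epithelial transcripts, which the EPCAM gate should remove, were present in small intestinal GFP-negative libraries and nearly absent from GFP-positive ones. The intermediate filament gene Krt8 fell by 6.30 ± 0.80, from 147 to 1.89 CPM, and the apolipoprotein gene Apob fell from 150 to 0.285 CPM. Myo7b, a brush border myosin, was at least 394-fold lower, from 38.6 to 0 CPM. Of 14 epithelial markers 12 fell and none rose (list adjusted p = 4.13e-15, and adjusted p = 0.148 with an estimated correlation). Of 11 small intestinal epithelial genes 9 fell (list adjusted p = 7.73e-12, and adjusted p = 0.0979 with an estimated correlation), and of 9 colonic epithelial genes 2 fell (adjusted p = 0.0102, and adjusted p = 0.487 with an estimated correlation). Leukocyte markers had no called member and a median of -4.98. Their list adjusted p of 0.0138 rose to 0.578 without GFP-negative replicate 3, the library that held most of them, and adjusted p = 0.627 with an estimated correlation. B and plasma cell markers, with 1 of 6 lower over all genes and 5 of 6 adjusted over the list alone, were not called as a list (adjusted p = 0.0716, 0.578 without GFP-negative replicate 3 and 0.00991 with the replicate block). The called member, Cd79a, lost its call in 4 of the 6 fits without a library, with 0.407 without that replicate.

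Complement genes were the most uniform immune group in small intestinal GFP-positive cells, with 8 of 11 higher (4 without GFP-positive replicate 3) and none lower. C3, the central complement component, rose from 1180 to 9170 CPM (log2 2.96 ± 0.28, adjusted p = 1.37e-04), and the terminal component C7 rose by 2.36 ± 0.20 (adjusted p = 8.03e-05). The complement list gave an adjusted p = 1.11e-07, and adjusted p = 0.204 with an estimated correlation. Collagens were higher in 8 of 22 cases and lower in 2. Col14a1 rose from 764 to 3480 CPM (adjusted p = 5.53e-04), and Col12a1 fell by 2.07 ± 0.37 (adjusted p = 0.00355; list adjusted p = 2.46e-04, and adjusted p = 0.561 with an estimated correlation). Among stromal chemokines and cytokines 6 of 24 rose (4 without GFP-negative replicate 1) and 4 fell (1 without GFP-positive replicate 2), with a list adjusted p = 0.775. The lymphoid survival factor Il7 rose by 3.27 ± 0.47 (adjusted p = 0.00108), the alarmin Il33 by 1.72 ± 0.29, and the B cell chemoattractant Cxcl13 by 2.51 ± 0.41 (adjusted p = 0.00234), from 23.8 to 135 CPM. Retinoid genes split, with 2 of 9 higher and 2 lower, and the retinaldehyde dehydrogenase Aldh1a3 fell from 344 to 79 CPM. In the prostaglandin list the degrading enzyme Hpgd rose by 3.14 ± 0.38 and the synthase Ptgs1 fell by 1.89 ± 0.30. Of the gut mesenchyme transcription factors 3 of 16 rose and 5 fell, with Osr1 higher by 2.31 ± 0.34 and Tbx2 and Tbx3 lower by a log2 of -2.71 ± 0.33 and -2.83 ± 0.36. Neither the retinoid (adjusted p = 0.775), prostaglandin (0.545) nor transcription factor list (0.273) was called. The same held for interferon response (0.732), antigen presentation (0.902), anterior Hox (0.902), posterior Hox (0.685), cell cycle (0.114) and nuclear RNAs (0.775).

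RNA quality measures also differed between the small intestinal sorts. The genes mt-Rnr1 and mt-Rnr2 took 9.73% to 12.66% of counts in GFP-negative and 5.35% to 7.92% in GFP-positive libraries. Protein-coding genes took 65.93% to 76.12% and 78.86% to 83.84%. Mitochondrial mRNAs were lower in 5 of 12 cases, or 1 without GFP-negative replicate 1 (list adjusted p = 3.69e-04, and adjusted p = 0.364 with an estimated correlation). The immediate early and stress list was called as higher (adjusted p = 0.0101), with 1 of 17 members called, Dusp1 at 1.77 ± 0.39. Its adjusted p was 0.273 without GFP-negative replicate 3, and adjusted p = 0.686 with an estimated correlation.

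In all, 1821 of 16757 genes were called in the small intestine, 710 higher and 1111 lower, and 3957 had an unadjusted p under 0.05. For 21.9% of the tested genes all 3 libraries of one group lay above all 3 of the other, where chance gives 10%. Leaving out 1 library gave 1239 to 2644 calls and kept as few as 1150 of the 1821. Of 115 called named genes, many picked by effect size or adjusted p, 93 kept their call in all 6 fits. With limma-voom Wnt2, Areg, Apob and Alox12e were no longer called, and on the deposited log2 scale Wnt4, Fgf10, Kitl, Areg, Tbx3 and Myo7b were not. When the fit held only the libraries compared, 850 genes were called, 835 of them also in the main fit. In that fit Fgf10, Gas6, Wnt2b and Dusp1 were not called. With a replicate block, since the numbers may pair the small intestinal sorts, 1931 genes were called, 1506 of them also called without it. The block ended the calls of Wnt10b (adjusted p from 0.0422 to 0.0727) and Dkk2 (0.035 to 0.0634) and added Chrd, Frzb and Nrg1 at adjusted p of 0.0335, 0.0103 and 0.03.

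In the colon, GFP-positive cells again carried more Grem1 and Rspo2, and far less of most BMP ligands. Grem1 rose by 3.11 ± 0.39 (adjusted p = 4.89e-04), from 93.5 ± 17.5 to 807 ± 57.8 CPM. Rspo2 rose from 0.207 to 2.34 CPM (adjusted p = 0.0205), but its call ended in 4 of the 6 fits without a library, with 0.103 without GFP-negative replicate 2, and Rspo1 was not called at 0.36 (adjusted p = 0.77). The R-spondin list, which holds the sorted gene, was called (adjusted p = 0.00329, and adjusted p = 0.127 with an estimated correlation). Of 8 BMP ligands 6 fell and none rose (list adjusted p = 1.56e-07, and adjusted p = 0.132 with an estimated correlation). Bmp7 (chromosome 2, 172868012 to 172940321) fell by 5.13 ± 0.57 (adjusted p = 3.42e-04), from 112 to 3.17 CPM, and Bmp3 (chromosome 5, 98854415 to 98884396) by 5.11 ± 0.62 (adjusted p = 5.91e-04), from 172 to 5.01 CPM. Bmp5 fell from 406 to 21.5 CPM, Bmp4 from 456 to 106 CPM and Bmp2 from 146 to 34.8 CPM, with adjusted p of 4.63e-04, 5.98e-04 and 0.00338. Bmp6 fell by 1.16 ± 0.29, a call that ended in 5 of the 6 fits without a library, with 0.115 without GFP-positive replicate 2. The non-canonical ligand Wnt5a (chromosome 14, 28504750 to 28527448) fell by 2.88 ± 0.26 (adjusted p = 6.42e-05), from 133 to 18 CPM, with Wnt5b lower by a log2 of -2.81 ± 0.51 and Wnt4 by -4.03 ± 0.37. Wnt2 and Wnt2b were not called, at -1.15 and 0.19. The Wnt ligand list, with 3 of 10 lower and none higher, was not called (adjusted p = 0.171).

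Several Wnt antagonists, EGF family ligands and other growth factors were also lower in colonic GFP-positive cells. Sostdc1 fell by 5.47 ± 0.93 (adjusted p = 0.00274). Wif1, a Wnt inhibitory factor, fell by 5.44 ± 1.41 (adjusted p = 0.0307), a call that ended in 5 of the 6 fits without a library, with 0.123 without GFP-positive replicate 2. Of 8 Wnt antagonists 3 fell, or 0 without GFP-negative replicate 3 (list adjusted p = 0.00117, and adjusted p = 0.0835 with an estimated correlation). The neuregulin Nrg1 fell by 5.33 ± 0.96 (adjusted p = 0.00653), from 100 to 2.46 CPM, and epiregulin (Ereg) from 238 to 39.2 CPM, and 3 of 8 EGF family ligands fell (list adjusted p = 7.64e-04, and adjusted p = 0.2 with an estimated correlation). Hgf, the hepatocyte growth factor, fell by 2.62 ± 0.31 (adjusted p = 3.83e-04), Vegfa by 1.64 ± 0.28 and Kitl by 1.91 ± 0.37. The other growth factor list (2 of 19 higher and 4 lower, or 0 and 3 without GFP-negative replicate 1, adjusted p = 0.104) and the BMP antagonist list (1 of 12 higher, 2 lower, adjusted p = 0.244) were not called. Hedgehog targets fell in 3 of 8 cases, among them the receptor Ptch1 from 468 to 148 CPM (adjusted p = 0.00165; list adjusted p = 0.00291, and adjusted p = 0.409 with an estimated correlation). Of 10 Wnt targets 2 fell (list adjusted p = 0.00429, and adjusted p = 0.116 with an estimated correlation).

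**Figure D2:**
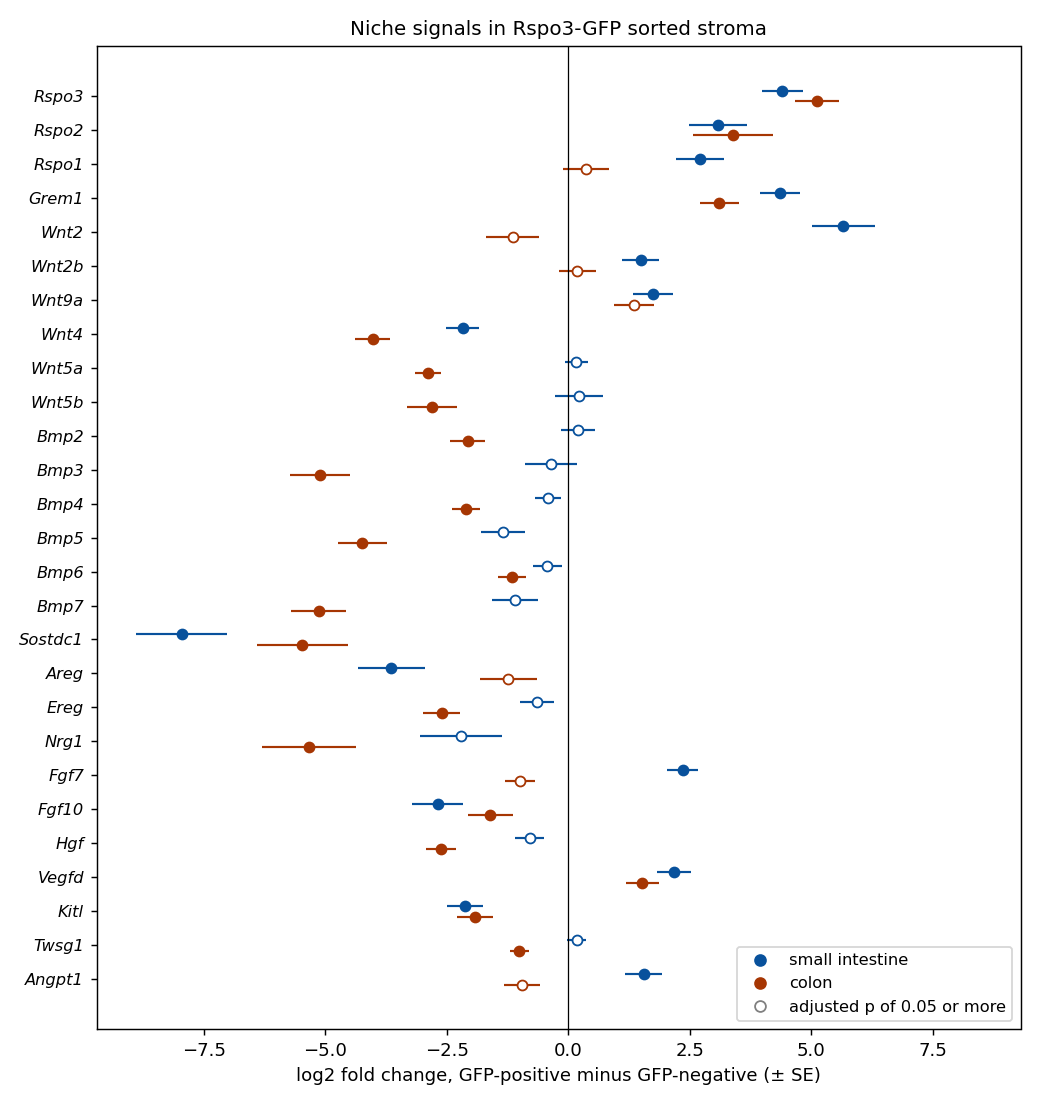
Log2 fold change of GFP-positive minus GFP-negative cells for niche genes in the small intestine (blue) and colon (orange), with bars of 1 SE from edgeR and open points where the gene was not called. BMP ligands, Wnt5a and Wnt5b fell in the colon and were not called in the small intestine.

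Cell type markers in the colon showed the strongest rise for lymphatic endothelium and the strongest fall for telocytes. Lyve1 rose by 7.60 ± 0.87 (adjusted p = 4.74e-04), from 13.1 to 2540 CPM, Mmrn1 from 31.8 to 6070 CPM, Reln from 13.9 to 2320 CPM and Flt4, the receptor of lymphangiogenic VEGFs, from 16.4 to 1770 CPM. Of 11 lymphatic markers 9 rose over all genes and 11 adjusted over the list alone (list adjusted p = 9.63e-15, and adjusted p = 0.0835 with an estimated correlation). Markers common to all endothelium rose in 10 of 12 cases, or 3 without GFP-negative replicate 2, with the tyrosine kinase receptor Tek from 57.3 to 301 CPM (list adjusted p = 1.5e-08, and adjusted p = 0.23 with an estimated correlation). Pecam1 (CD31) rose from 94.6 to 631 CPM (adjusted p = 0.0108), and without GFP-negative replicate 2 its adjusted p was 0.0532. Blood endothelial markers split, 3 of 13 higher (1 without GFP-negative replicate 2), such as Gpihbp1 at 5.87 ± 0.69, and 5 lower (2 without GFP-negative replicate 1), such as Flt1 at -4.68 ± 0.71. That list had an adjusted p = 0.0206, 0.112 without GFP-negative replicate 1, and adjusted p = 0.525 with an estimated correlation. Telocyte markers fell in 11 of 14 cases and in all 14 adjusted over the list alone (median -3.95, list adjusted p = 5.59e-15, and adjusted p = 0.0835 with an estimated correlation). The transcription factor Sox6 fell from 119 to 3.29 CPM (adjusted p = 0.00152), and Bmp3, Bmp5, Bmp7, Wnt5a and Nrg1 belong to this list as well. Trophocyte markers rose in 6 of 14 cases, with Ackr4 from 23.8 to 247 CPM (adjusted p = 4.56e-05; list adjusted p = 6.51e-05, and adjusted p = 0.2 with an estimated correlation). General fibroblast markers were not called as a list (2 of 13 lower, adjusted p = 0.249). Among them Pdgfra fell from 1210 to 468 CPM (adjusted p = 0.0166), a call that ended in all 6 fits without a library, with a highest adjusted p of 0.0777 without GFP-positive replicate 2.

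**Figure D3:**
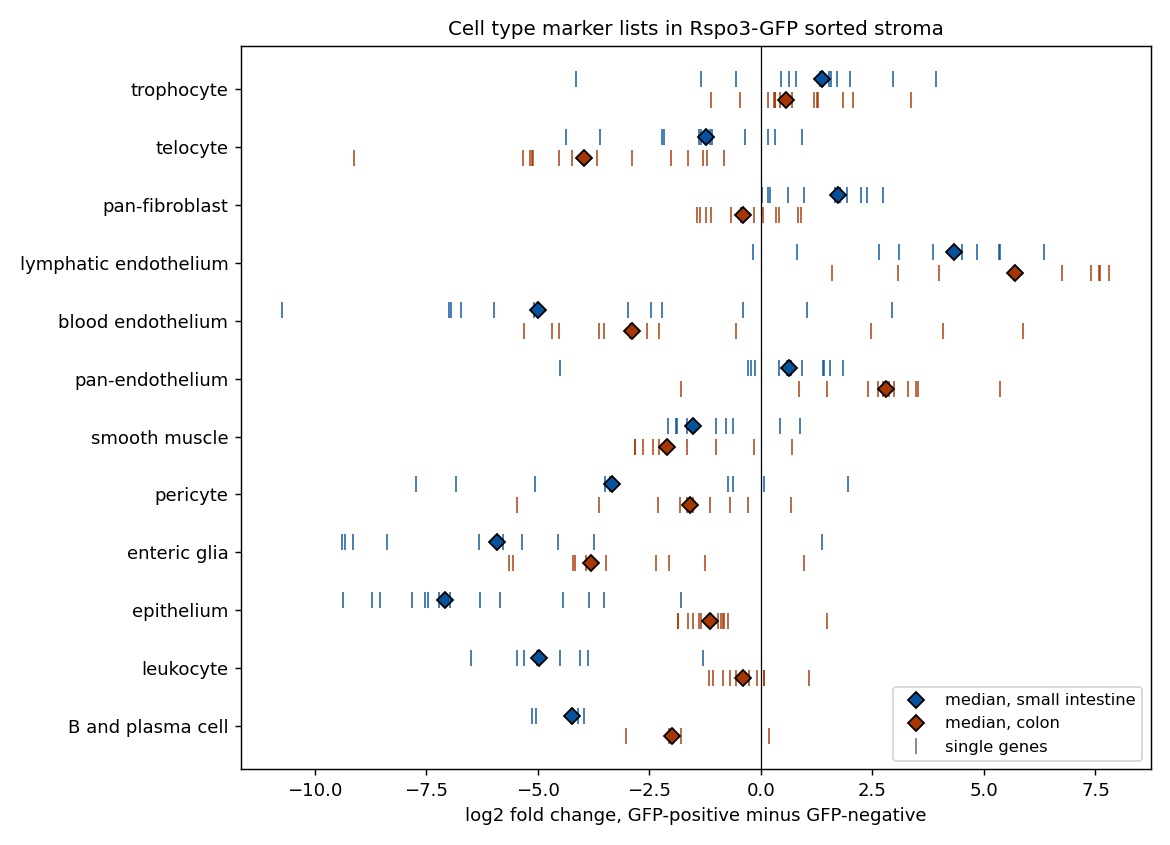
Log2 fold change of GFP-positive minus GFP-negative cells for the tested genes of 12 cell type marker lists (ticks) with list medians (diamonds), small intestine in blue and colon in orange. The lymphatic median is 4.34 in the small intestine and 5.70 in the colon, and the telocyte median is -1.23 and -3.95.

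Most smooth muscle markers fell in colonic GFP-positive cells. Myh11 fell from 1980 to 279 CPM and the smooth muscle actin Acta2 from 814 to 116 CPM, and 8 of 11 smooth muscle markers were lower (list adjusted p = 8.58e-07, and adjusted p = 0.23 with an estimated correlation). Pericyte markers fell in 5 of 10 cases, or 3 without GFP-negative replicate 1, with Cspg4 lower by a log2 of -1.81 ± 0.33 (list adjusted p = 3.35e-04, and adjusted p = 0.348 with an estimated correlation). Gfap fell by 5.56 ± 0.91 (adjusted p = 0.00257), and of 11 glial markers 4 fell and 1 rose, or 2 and 0 without GFP-negative replicate 1 (list adjusted p = 1.79e-05, and adjusted p = 0.127 with an estimated correlation). Kit, the receptor that marks interstitial cells of Cajal, fell from 31.4 to 2.75 CPM, though its call (adjusted p = 0.0222) ended in 5 of the 6 fits without a library, with 0.104 without GFP-positive replicate 2. The other called markers among the 4 of that cell, Etv1 and Ano1, lost their calls in 6 and 5 of those fits, with 0.151 and 0.181 without the same library (list adjusted p = 0.0149, and adjusted p = 0.23 with an estimated correlation). Epithelial genes had 1 of 14 lower over all genes and none adjusted over the list alone, with a median of -1.14 (list adjusted p = 0.00248, and adjusted p = 0.476 with an estimated correlation). Colonic epithelial genes had none of 9 called, and their list adjusted p of 0.0149 rose to 0.133 without GFP-positive replicate 1, with adjusted p = 0.435 with an estimated correlation. Neuronal (0.0917, and 0.0285 with a replicate block), mesothelial (0.278, median -0.86 and mean 1.90), leukocyte (0.751), B and plasma cell (0.168) and small intestinal epithelial lists (0.109) were not called.

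Among matrix, immune and regional genes of the colon, Col15a1, a basement membrane collagen, fell from 897 to 155 CPM (adjusted p = 3.86e-04) and Col12a1 from 1400 to 289 CPM. Of 22 collagens 3 rose and 5 fell (list adjusted p = 0.0108, and adjusted p = 0.545 with an estimated correlation or 0.0518 with a replicate block). C3 rose from 1350 to 4820 CPM and C7 by 2.28 ± 0.20 (adjusted p = 6.42e-05), with 3 of 11 complement genes higher (list adjusted p = 0.0206, and adjusted p = 0.502 with an estimated correlation or 0.0582 with a replicate block). Il7 rose from 5.81 to 55.5 CPM, Il33 by 2.20 ± 0.30, and Cxcl13 fell from 31.3 to 3.89 CPM (adjusted p = 0.00124; chemokine and cytokine list adjusted p = 0.368). Interferon response genes rose in 5 of 18 cases, or 2 without GFP-negative replicate 2, with Ifi44 at 2.96 ± 0.50 (list adjusted p = 3.35e-04, and adjusted p = 0.353 with an estimated correlation). Antigen presentation genes, none of 13 called, had an adjusted p = 0.0149, 0.0653 without GFP-negative replicate 2, and adjusted p = 0.476 with an estimated correlation. Retinoid genes fell in 5 of 9 cases and rose in 2, with the retinol carrier Rbp4 from 42.7 to 4.23 CPM and Aldh1a1 from 211 to 62.7 CPM. The retinoid list had an adjusted p = 0.0238, 0.0632 without GFP-negative replicate 1, 0.0901 with a replicate block, and adjusted p = 0.367 with an estimated correlation. Anterior Hox genes rose in 6 of 21 cases, or 3 without GFP-negative replicate 3, such as Hoxd8 at 1.99 ± 0.31 (list adjusted p = 6.79e-04, and adjusted p = 0.224 with an estimated correlation). Hoxa13, the most posterior member of its cluster, fell from 29 to 4.55 CPM (adjusted p = 0.00327; posterior Hox list adjusted p = 0.0122, and adjusted p = 0.224 with an estimated correlation). Of 16 gut mesenchyme transcription factors 7 fell and 2 rose, with Tbx2 lower by a log2 of -4.44 ± 0.37 and Tbx3 by -4.34 ± 0.39 (list adjusted p = 0.00114, and adjusted p = 0.127 with an estimated correlation). The immediate early and stress list had no called member, and its adjusted p of 0.0145 rose to 0.124 without GFP-positive replicate 1, with adjusted p = 0.576 with an estimated correlation. Prostaglandin (0.263), cell cycle (0.268), nuclear RNA (0.347) and mitochondrial lists (0.0969) were not called.

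The colon comparison called 1456 genes, 775 higher and 681 lower, with 3265 at an unadjusted p under 0.05, and the groups did not overlap for 35.6% of tested genes, where chance gives 10%. The count fell to 871 without GFP-negative replicate 2, 911 without GFP-negative replicate 3, 884 without GFP-positive replicate 1 and 816 without GFP-positive replicate 2. A fit without a library kept as few as 808 of the calls, and 81 of 109 called named genes kept theirs in all 6. The deposited log2 scale ended the calls of Sostdc1, Vegfa, Rspo2, Gfap and Kit, and limma-voom those of Rspo2, Gfap and Kit. A replicate block called 1535 genes and ended the calls of Rspo2, Bmp6 and Pdgfra. A fit to only the libraries compared called 3016 genes, 1424 of them also in the main fit.

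The GFP effects of the tissues overlapped well beyond the number that independent calls would give. There were 287 genes higher in both tissues, where independent calls would give 32.84, and 258 lower in both, where they would give 45.15, a total of 545 in the same direction. Another 25 were called in opposite directions, where 80.24 would be found by independent calls. Across genes the log2 fold changes correlated at Pearson r = 0.471 and Spearman rho = 0.42, as a description, since genes are not independent replicates. Shared increases included Rspo3, Grem1, Ackr4, C3, C7, Il7, Lyve1, Mmrn1 and Reln, and shared decreases included Wnt4, Sostdc1, Kitl, Tbx2, Tbx3, Myh11, Cspg4 and Gfap. Cxcl13 rose by 2.51 in the small intestine and fell by 3.01 in the colon, and Osr1, a mesenchymal transcription factor, had 2.31 and -1.86, and the difference between the tissues was called for both.

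The difference between the GFP effects was tested directly, as the colon effect minus the small intestinal effect. Bmp3 and Bmp7 had differences of -4.75 ± 0.79 (adjusted p = 0.018) and -4.04 ± 0.71 (adjusted p = 0.0196), so the GFP effect was more negative in the colon. Bmp5 (-2.89 ± 0.64), Bmp2 (-2.27 ± 0.50) and Bmp4 (-1.69 ± 0.38) were called at adjusted p of 0.0432, 0.0413 and 0.0425. Of the 12 fits without a library, 3 ended the call of Bmp3, 3 that of Bmp7, 10 those of Bmp4 and of Bmp5, and 9 that of Bmp2. The highest adjusted p were 0.0565, 0.0606, 0.115 and 0.122 for Bmp3, Bmp7, Bmp5 and Bmp4 without colonic GFP-negative replicate 2, and 0.114 for Bmp2 without colonic GFP-positive replicate 2. A replicate block ended the calls of Bmp2, Bmp4 and Bmp5. Of 8 BMP ligands 5 were called, all more negative in the colon (list adjusted p = 3.06e-06, and adjusted p = 0.194 with an estimated correlation). Wnt2 at -6.80 ± 0.84 (adjusted p = 0.00311) and Wnt5a at -3.05 ± 0.35 (adjusted p = 0.00247) kept their calls in all 12 fits without a library, as did Fgf7 at -3.35 ± 0.44 (adjusted p = 0.00408). Wnt2 lost it with limma-voom, and Wnt2 and Wnt5a lost it on the deposited log2 scale. The Wnt ligand list, with 3 of 10 members called and 5 adjusted over the list alone, was called with the preset correlation (adjusted p = 3.39e-06) and with an estimated one (adjusted p = 0.0334). Neither Rspo3 (0.70 ± 0.55, adjusted p = 0.65), Grem1 (-1.25 ± 0.52, adjusted p = 0.28) nor Rspo1 (-2.35, adjusted p = 0.0983) was called, and the R-spondin list was not (adjusted p = 0.3).

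Genes outside the niche lists whose GFP effect differed included Cxcl13 (-5.52 ± 0.60, adjusted p = 0.0023), Osr1 (-4.17 ± 0.47), the G protein subunit Gnai1 (-3.73 ± 0.41), the fibrillin Fbn2 (-3.71 ± 0.44) and the iron reductase Cybrd1 (-4.20 ± 0.53). The matricellular protein Postn (-2.94 ± 0.40, adjusted p = 0.00454) and the type IV collagen Col4a5 (-2.87 ± 0.46, adjusted p = 0.0109) also had a more negative effect in the colon, and each of these 7 kept its call in every fit without a library, though Fbn2 lost it on the deposited log2 scale. Of 14 telocyte markers 5 were called as more negative in the colon, or 2 without colonic GFP-negative replicate 2, and none as more positive (list adjusted p = 3.63e-09, and adjusted p = 0.163 with an estimated correlation). General fibroblast markers had 5 of 13 called, 0 without small intestinal GFP-negative replicate 1, and 11 adjusted over the list alone, all more negative in the colon (adjusted p = 5.3e-11, and adjusted p = 0.255 with an estimated correlation). Collagens had 7 of 22 called in that direction, 1 without colonic GFP-negative replicate 2, and 14 adjusted over the list alone (adjusted p = 1.23e-10, and adjusted p = 0.255 with an estimated correlation). Complement genes had 1 of 11 called, and 7 adjusted over the list alone (adjusted p = 1.92e-04, and adjusted p = 0.28 with an estimated correlation). Called epithelial genes went the other way. The brush border myosin gene Myo1a (8.35 ± 1.22) and the inflammasome gene Nlrp6 (6.64 ± 0.89, adjusted p = 0.00454) kept their calls in every fit without a library, though not with limma-voom. Of 14 epithelial markers 6 were called, or 0 without small intestinal GFP-negative replicate 1 (list adjusted p = 4.61e-12, and adjusted p = 0.194 with an estimated correlation). The lists of all endothelium (1 of 12 called, adjusted p = 1.07e-06, and adjusted p = 0.288 with an estimated correlation) and of glia (1 of 11 called, adjusted p = 7.19e-06, and adjusted p = 0.194 with an estimated correlation) were called as more positive in the colon, with a fry adjusted p of 0.078 for all endothelium.

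The interaction called 345 genes, 195 more positive and 150 more negative in the colon, with 2430 at an unadjusted p under 0.05. This count is the least stable of the 5. It was 145 without small intestinal GFP-negative replicate 1 and 1044 without GFP-negative replicate 2 of that tissue, and 111 and 117 without its GFP-positive replicates 1 and 3. In the colon it was 223, 69 and 72 without GFP-negative replicates 1, 2 and 3, and 98 and 165 without GFP-positive replicates 2 and 3. Such a fit kept as few as 67 of the 345 calls, and 14 of 55 called named genes kept theirs in all 12.

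Between GFP-positive cells of the colon and small intestine, Rspo3 and Grem1 were not called (-0.55 ± 0.36, adjusted p = 0.52, and -0.36, adjusted p = 0.72), while Rspo2 was lower in the colon by a log2 of -4.12 ± 0.64 (adjusted p = 0.00288), 41.2 against 2.34 CPM. Rspo1 was lower too (16.8 against 3.51 CPM, adjusted p = 0.0175), but 3 of the 6 fits without a library ended the call, with 0.0757 without small intestinal GFP-positive replicate 3. The R-spondin list was called as lower in the colon (adjusted p = 0.00146, and adjusted p = 0.0781 with an estimated correlation). Wnt2 was lower by a log2 of -4.19 ± 0.58 (adjusted p = 0.00182). The Wnt ligand list, with 2 of 10 lower, had an adjusted p = 0.0227, 0.072 without colonic GFP-positive replicate 2, and adjusted p = 0.149 with an estimated correlation. The Wnt antagonists Dkk2 and Sfrp1 were lower in the colon, 105 against 2.93 and 1720 against 328 CPM (adjusted p = 0.00172 and 0.00219). Wnt targets were lower in 3 of 10 cases, with Apcdd1 at -2.48 ± 0.40 (list adjusted p = 0.00146, and adjusted p = 0.0781 with an estimated correlation). Fgf9 (2.94 ± 0.35) and Fgf10 (3.44 ± 0.53) were higher in the colon, and the growth factor midkine (Mdk) was lower (-3.49 ± 0.49). No BMP ligand was called, and neither were the lists of BMP ligands (adjusted p = 0.469), BMP antagonists (0.603), Wnt antagonists (0.311), EGF family (0.979), other growth factors (0.603) or hedgehog targets (0.429).

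Most retinoid genes tested were lower in colonic GFP-positive cells. Lrat, which esterifies retinol for storage (chromosome 3, 82892579 to 82903973), was lower by a log2 of -9.62 ± 0.69 (adjusted p = 9.19e-05), 197 against 0.234 CPM. The cytochrome P450 gene Cyp1b1 (chromosome 17, 79701537 to 79715061) was lower by -6.86 ± 0.41 (adjusted p = 9.32e-06), 553 against 4.76 CPM. Cyp1a1 was at least 343-fold lower, with 40.5 against 0 CPM, and Ahrr, the repressor of the aryl hydrocarbon receptor, was lower by -5.78 ± 0.72 (adjusted p = 0.00126). Aldh1a2, which makes retinoic acid, was 124 against 14.5 CPM (adjusted p = 9.56e-04), and the retinoic acid hydroxylase Cyp26b1 was 227 against 2.93 CPM (adjusted p = 0.0151, and 0.0831 without colonic GFP-positive replicate 3 or 0.0608 without replicate 2). Of 9 retinoid genes 6 were lower, or 3 without colonic GFP-positive replicate 2, and none higher (list adjusted p = 4.76e-08, and adjusted p = 0.0781 with an estimated correlation). Complement genes were lower in 4 of 11 cases, or 2 without small intestinal GFP-positive replicate 3, with C7 864 against 245 CPM (adjusted p = 6.5e-04; list adjusted p = 3.74e-08, and adjusted p = 0.172 with an estimated correlation). Cxcl13 was 135 against 3.89 CPM (adjusted p = 4.4e-04; chemokine and cytokine list adjusted p = 0.318). Interferon response genes were higher in 4 of 18 cases (1 without small intestinal GFP-positive replicate 3), with Gbp3 at 1.39 ± 0.21, and their list adjusted p of 0.00392 rose to 0.0644 without small intestinal GFP-positive replicate 3, with adjusted p = 0.673 with an estimated correlation. Antigen presentation genes, none of 13 called, had adjusted p = 2.94e-04, and adjusted p = 0.43 with an estimated correlation.

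Positional and epithelial genes separated the GFP-positive cells of the tissues. The EPCAM gate should remove epithelial cells. Whether the epithelial transcripts came from such cells or their RNA in the colonic GFP-positive libraries was not tested. Hoxa13 (chromosome 6, 52257694 to 52260880) was higher in the colon by 6.62 ± 0.68 (adjusted p = 8.02e-04) and Hoxd11 (chromosome 2, 74679557 to 74687016) at least 46.8-fold, and 7 of 11 posterior Hox genes were higher, or 4 without small intestinal GFP-positive replicate 1. That list was called with the preset correlation (adjusted p = 6.74e-16) and with an estimated one (adjusted p = 0.00713). Of 21 anterior Hox genes 8 were lower in the colon (2 without colonic GFP-positive replicate 3) and 1 higher, with Hoxa2 at -3.78 ± 0.59 and Hoxc4 at -4.52 ± 0.82 (list adjusted p = 1.16e-04, and adjusted p = 0.193 with an estimated correlation). Epithelial markers were higher in 10 of 14 cases, with Krt8 at 390 against 1.89 CPM and the mucin Muc3 at 154 against 0.105 CPM (list adjusted p = 3.2e-19, and adjusted p = 0.0781 with an estimated correlation). Colonic epithelial genes were higher in 6 of 9 cases, or 3 without small intestinal GFP-positive replicate 1, with Car1 at least 251-fold (list adjusted p = 4.41e-11, and adjusted p = 0.0781 with an estimated correlation). Small intestinal epithelial genes were not called as a list (adjusted p = 0.712). The lists of general fibroblast markers (1 of 13 lower, 8 adjusted over the list alone, adjusted p = 5.5e-06, and adjusted p = 0.624 with an estimated correlation) and collagens (2 of 22 lower, adjusted p = 0.00144, and adjusted p = 0.702 with an estimated correlation) were called as lower in the colon. Cell cycle genes, none called, were higher as a list (adjusted p = 0.00166, and adjusted p = 0.698 with an estimated correlation). Smooth muscle (adjusted p = 0.0205, and 0.095 without small intestinal GFP-positive replicate 2) and immediate early and stress genes (adjusted p = 0.00308, and 0.108 without replicate 1 of that group) had adjusted p = 0.702 and adjusted p = 0.735 with an estimated correlation. The lists of trophocytes (0.273), telocytes (0.603), lymphatic (0.0534, and 0.00882 with a replicate block), blood (0.921) and all endothelium (0.0677, and 0.0112 with the block), and of pericytes (0.661), glia (0.396) and leukocytes (0.449), were not called.

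Between tissues in GFP-positive cells 765 genes were called, 461 higher and 304 lower in the colon, with 2738 at an unadjusted p under 0.05 and no overlap for 24.7% of tested genes (10% by chance). The count was 439 and 481 without small intestinal GFP-positive replicates 1 and 3, and 416 and 432 without colonic GFP-positive replicates 2 and 3. Of 85 named genes that were called, 48 kept their call in all 6 fits without a library. Calls for Wnt2, Muc3, Cyp1a1, Hoxa2 and Hoxc4 ended with limma-voom, and those for Fgf9, Rspo1, Hoxa2, Hoxa13 and Hoxd11 on the deposited log2 scale.

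**Figure D4:**
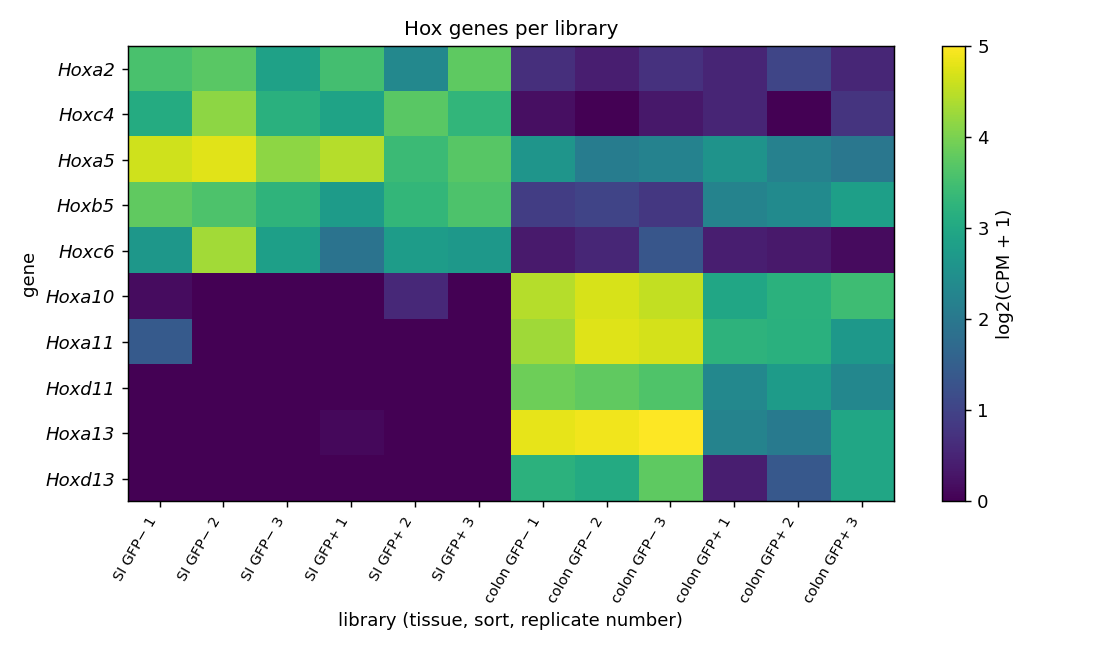
Log2 of CPM plus 1 for 10 Hox genes in each of the 12 libraries (SI is small intestine). Hoxa10 to Hoxd13 are above 0.3 CPM in all colonic libraries and mostly at 0 in small intestinal ones, and Hoxa2 to Hoxc6 have higher group means in the small intestine.

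In GFP-negative cells the colon carried more BMP and non-canonical Wnt ligands than the small intestine. Bmp3 was higher in the colon by 3.22 ± 0.56 (adjusted p = 0.0113), 172 against 18.5 CPM, Bmp4 by 1.72 ± 0.28 (adjusted p = 0.00563), 456 against 138 CPM, and Bmp2 and Bmp6 by 2.04 ± 0.36 and 1.70 ± 0.29. Bmp7 and Bmp5 were also called (2.25 ± 0.49 and 2.36 ± 0.46), but lost their calls in 4 and 3 of the 6 fits without a library, with adjusted p of 0.0936 and 0.067 without colonic GFP-negative replicate 3. Of 8 BMP ligands 6 were higher and none lower (list adjusted p = 9.83e-07, and adjusted p = 0.182 with an estimated correlation). Wnt5a was 133 against 34.1 CPM (adjusted p = 0.00174) and Wnt5b was higher by 3.04 ± 0.52. Of 10 Wnt ligands 5 were higher, but Wnt2, Wnt4 and Wnt10b lost their calls in 6, 5 and 3 of the 6 fits without a library, with 0.105 for Wnt2 without colonic GFP-negative replicate 2 and 0.0957 and 0.0965 for the others without replicate 3 (list adjusted p = 9.04e-04, and adjusted p = 0.0693 with an estimated correlation). Fgf7 was 45.4 against 6.11 CPM (adjusted p = 0.00112), and Fgf9 was higher by 2.63 ± 0.34. Rspo3 (-1.25, adjusted p = 0.123) and Grem1 (0.89, adjusted p = 0.218) were not called. Rspo2 was lower in the colon, 0.207 against 4.82 CPM (adjusted p = 0.0106, and 0.0643 without colonic GFP-negative replicate 2). The R-spondin list was lower (adjusted p = 0.0442, and 0.0882 without small intestinal GFP-negative replicate 2 or 0.0555 with a replicate block), with adjusted p = 0.271 with an estimated correlation. The BMP antagonist list (2 of 12 higher, adjusted p = 0.0149) and the other growth factor list (4 of 19 higher, 2 without small intestinal GFP-negative replicate 1, and 1 lower, adjusted p = 0.0127) lost their calls without small intestinal GFP-negative replicates 1 and 3 (0.0818 and 0.0666). They had adjusted p = 0.391 and adjusted p = 0.34 with an estimated correlation. Wnt antagonists (0.411), EGF family (0.108) and Wnt targets (0.0914) were not called as lists, and hedgehog targets were (1 of 8 higher, adjusted p = 0.00234, and adjusted p = 0.354 with an estimated correlation).

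Telocyte markers were higher in colonic GFP-negative cells in 7 of 14 cases, or 4 without colonic GFP-negative replicate 2, with Postn at 3060 against 209 CPM (3.87 ± 0.31, adjusted p = 1.25e-04; list adjusted p = 3.97e-11, and adjusted p = 0.0693 with an estimated correlation). Trophocyte markers were higher in 5 of 14 cases (1 without colonic GFP-negative replicate 3) and lower in 1 (list adjusted p = 0.00423, and adjusted p = 0.34 with an estimated correlation). General fibroblast markers, none of 13 called and 5 adjusted over the list alone, were higher as a list (adjusted p = 7.52e-06, and adjusted p = 0.354 with an estimated correlation). Of 22 collagens 6 were higher (3 without small intestinal GFP-negative replicate 1) and 1 lower, with the basement membrane chains Col4a5 and Col4a6 at 2.39 ± 0.33 and 2.90 ± 0.38 (list adjusted p = 2.52e-06, and adjusted p = 0.34 with an estimated correlation). The lists of blood endothelium (3 of 13 lower, 0 without colonic GFP-negative replicate 2, adjusted p = 4.51e-08, and adjusted p = 0.252 with an estimated correlation), all endothelium (none of 12 called, adjusted p = 7.29e-06, and adjusted p = 0.34 with an estimated correlation) and glia (3 of 11 lower, 0 without small intestinal GFP-negative replicate 1, adjusted p = 3.7e-06, and adjusted p = 0.102 with an estimated correlation) were called as lower in the colon. The lymphatic (1 of 11 lower, adjusted p = 0.0449, and adjusted p = 0.498 with an estimated correlation) and neuronal lists (none of 8 called, adjusted p = 0.00684, and adjusted p = 0.396 with an estimated correlation) lost their calls without small intestinal GFP-negative replicate 1, at 0.452 and 0.106. The list of interstitial cells of Cajal was called as higher (1 of 4 called, adjusted p = 0.0127, 0.0511 without small intestinal GFP-negative replicate 2, and adjusted p = 0.271 with an estimated correlation).

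Hox genes marked the position along the gut in GFP-negative cells as well. Hoxa13 was at least 233-fold higher in the colon, with 29 against 0 CPM, Hoxa10 was higher by 8.66 ± 1.00 (adjusted p = 0.00124), and 8 of 11 posterior Hox genes were higher, or 3 without colonic GFP-negative replicate 3. The posterior list was called with the preset correlation (adjusted p = 1.72e-17) and with an estimated one (adjusted p = 0.0048). Of 21 anterior Hox genes 11 were lower, or 7 without colonic GFP-negative replicate 2, and none higher, with Hoxb5 at -3.58 ± 0.42 and Hoxa5 at -2.47 ± 0.37 (list adjusted p = 8.76e-12, and adjusted p = 0.0693 with an estimated correlation). The hindlimb and hindgut factor Pitx1 was 131 against 4.66 CPM (adjusted p = 0.0028), though the transcription factor list was not called (adjusted p = 0.0662). Lrat was lower in the colon here too, 1.39 against 268 CPM (adjusted p = 1.32e-04), and of 9 retinoid genes 4 were lower (1 without colonic GFP-negative replicate 2) and 1 higher. The retinoid list had an adjusted p = 0.0107, 0.122 without small intestinal GFP-negative replicate 2, and adjusted p = 0.34 with an estimated correlation. Small intestinal epithelial genes were lower in 7 of 11 cases, or 2 without colonic GFP-negative replicate 2, with Apoa1 at 1.55 against 170 CPM and the lactase gene Lct at -8.29 (adjusted p = 0.00458; list adjusted p = 1.36e-09, and adjusted p = 0.102 with an estimated correlation). Colonic epithelial genes were higher in 4 of 9 cases, with Car1 at 118 against 0.648 CPM (list adjusted p = 5.53e-09, and adjusted p = 0.102 with an estimated correlation). General epithelial markers, 1 of 14 higher and 1 lower, were higher as a list (adjusted p = 0.00146, and adjusted p = 0.409 with an estimated correlation). Mitochondrial mRNAs (adjusted p = 0.00576, and 0.0514 without colonic GFP-negative replicate 2) and immediate early and stress genes (adjusted p = 0.0213, and 0.223 without small intestinal GFP-negative replicate 2) had no called member, and adjusted p = 0.34 and adjusted p = 0.596 with an estimated correlation. The median of either list changes sign on the deposited log2 scale. Complement (0.641), chemokine and cytokine (0.564), interferon (0.626), antigen presentation (0.128), prostaglandin (0.0662), smooth muscle (0.0846), pericyte (0.0541, and 0.0361 with a replicate block), leukocyte (0.077, and 0.0209), B and plasma cell (0.0644, and 0.022), cell cycle (0.743) and nuclear RNA lists (0.816) were not called.

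Between tissues in GFP-negative cells 706 genes were called, 369 higher and 337 lower in the colon, with 3055 at an unadjusted p under 0.05 and no overlap for 22.6% of tested genes (10% by chance). The count was 388 and 1229 without small intestinal GFP-negative replicates 1 and 2, and 396, 234 and 187 without colonic GFP-negative replicates 1, 2 and 3. Of 96 named genes that were called, 40 kept their call in all 6 fits without a library. Fits to only the libraries compared ended the calls of Rspo2 and Apoa1, and limma-voom those of Lct, Car1 and Rspo2. The tissue effects in GFP-positive and GFP-negative cells shared 165 calls in the same direction, 99 higher where independent calls would give 10.15 and 66 lower where they would give 6.114. In opposite directions there were 24, where 15.97 would be found by independent calls, and across genes the fold changes correlated at Pearson r = 0.381 and Spearman rho = 0.184.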

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

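The tests of cell content, labels and regrouping below were chosen only after the results were seen, and only the tests of scaling were written down before.

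Results are listed here because the GFP effect differed between colon and small intestine by the interaction term, for single genes or for a list. The term called 345 genes. Of 200 regroupings of the libraries within each tissue 100 were drawn, and 2 gave as many genes, the real one included. This share decides nothing about chance. The 85 draws that mix the sorts of both tissues put the GFP effects into the spread and called at most 1 gene. Of the 14 others, which keep the real groups of 1 tissue, 1 called more than the real grouping, 584. Values are log2, colon effect minus small intestinal effect. Epithelial genes were more positive in the colon, with Myo7b at 9.53 and Phgr1 at 7.51 (fitted values that depend on the prior count, since both are at 0 in small intestinal GFP-positive cells), Myo1a at 8.35, Slc5a1 at 7.68, Apob at 7.62, Ckmt1 at 7.20, Krt19 at 6.69 and Nlrp6 at 6.64. Clca3a1 was also more positive, at 6.54, but it rose with GFP in the colon (3.13) and fell in the small intestine (-3.415). More negative in the colon were the stromal genes Chodl at -5.81, Cxcl13 at -5.52, Rerg at -4.45, Cybrd1 at -4.20, Osr1 at -4.17, Gnai1 at -3.73 and Fbn2 at -3.71. Niche genes with that direction were Wnt2 at -6.80, Bmp3 at -4.75, Bmp7 at -4.04, Fgf7 at -3.35, Wnt5a at -3.05, Wnt5b at -3.02, Bmp5 at -2.89, Angpt1 at -2.50, Bmp2 at -2.27, Hgf at -1.83, Bmp4 at -1.69 and Twsg1 at -1.19.

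Lists that differed by this test are given by their median. More negative in the colon were telocyte markers (-2.92), Wnt ligands (-2.17), BMP ligands (-1.98), general fibroblast markers (-1.68), collagens (-1.42) and complement (-1.12). Posterior Hox genes, several at 0 in the small intestine, had a fitted -1.67, and -0.43 on the deposited log2 scale. Smaller negative medians were found for retinoid genes (-1.003), gut mesenchyme transcription factors (-0.98), smooth muscle (-0.92), hedgehog targets (-0.90), BMP antagonists (-0.86), other growth factors (-0.66) and Wnt antagonists (-0.65). More positive were small intestinal epithelium (6.24), epithelium (5.64), leukocytes (4.16), glia (3.01), blood endothelium (2.43), lymphatic endothelium (2.23), all endothelium (2.10), cell cycle (1.54), anterior Hox genes (0.83), interferon response (0.73) and mitochondrial mRNAs (0.48). With an estimated correlation, of these lists the Wnt ligands alone kept an adjusted p under 0.05 (0.0334). Without small intestinal GFP-negative replicate 3 the leukocyte, cell cycle, smooth muscle, retinoid and other growth factor lists had adjusted p of 0.696, 0.653, 0.0528, 0.0528 and 0.0528, and without colonic GFP-negative replicate 2 the mitochondrial list had 0.118.

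The 4 comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. The real split was the highest in each, so 1 of 10 gave as many genes. In the small intestine the real count was 1821 and the highest other 1, in the colon 1456 and 0, between tissues in GFP-positive cells 765 and 0, and in GFP-negative cells 706 and 1. Every other split mixes the real groups, which puts their difference into the spread, so its low count decides nothing about chance.

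The telocyte and BMP ligand lists had a more negative GFP effect in the colon, called with the preset correlation but not with an estimated one. Their list means differed by -2.32 ± 0.405 and -2.09 ± 0.495 (SE). Over 400 relabellings of the libraries within the tissues, the exact permutation p was 0.12 and 0.09. The median closest to 0 under the other scalings was -1.37 for telocyte markers and -1.83 for BMP ligands, both on the deposited log2 scale. With RLE factors and with library sizes only, the medians were -2.90 and -2.94 for telocyte markers and -1.97 and -2.01 for BMP ligands. The factors hardly moved them but nearly cancel in a difference of effects, so this decides nothing more about scaling. A difference in the fibroblast share of the libraries stays open, because relative to the general fibroblast list the differences of GFP effects were -0.456 ± 0.38 (SE) and -0.23 ± 0.346, within 2 SE of 0 also with the small intestinal sorts paired by number (SE 0.276 and 0.181). The general fibroblast list itself differed by -1.86 ± 0.525. Relative to it, the GFP effect was -2.66 in the small intestine and -3.12 in the colon for telocyte markers. For BMP ligands these values were -2.10 and -2.33. In the list means not set against fibroblasts, the tissues differed mainly in GFP-negative cells, with a mean log2 CPM of 6.85 in the colon and 4.75 in the small intestine for telocyte markers and 6.92 and 5.16 for BMP ligands, against 3.40 and 3.62, and 4.27 and 4.60, in GFP-positive cells. A biological difference between the tissues also stays open and was not tested apart from this.

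Epithelial genes were far lower in small intestinal GFP-positive cells. An exchange of small intestinal labels is argued against by Rspo3, which was 13.9 times higher in the lowest GFP-positive than in the highest GFP-negative library. Epithelial cells or their RNA in the GFP-negative libraries may explain it, since small intestinal epithelial genes had a median of -6.77 between colonic and small intestinal GFP-negative cells while colonic epithelial genes were higher. The sort excluded EPCAM-positive cells, and Krt8, one of the abundant genes, measured 147 CPM. No biological explanation was tested.

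Immunoglobulin genes took 8.23% of the counts of small intestinal GFP-negative replicate 3, against 0.0283% to 0.310% in the other libraries, with Igkc at 34900 CPM against 684 and 576 in the replicates. That this library alone makes the small intestinal calls is argued against, since 1362 of the 1821 genes were also called without it. B or plasma cells in that library remain a candidate source, as their other markers were higher by a median log2 of 5.75 than in the higher of the other replicates. Over 6 T cell and myeloid markers the median was 6.07, from myeloid genes such as Csf1r (6.98) and Lyz2 (5.76), while Cd3d, the T cell gene among them, was higher by 0.456. Myeloid cells may therefore have entered as well despite the CD45 gate, and Ptprc, which encodes CD45, measured 304 CPM against 6.73 and 1.78. No biological explanation was tested.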

How the results depend on the processing

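The alternatives were planned, except those named above as added after the data were seen. Taking log2(TPM + 1) again from the deposited values returns the same numbers and was not run. A fit to only the libraries compared does not apply to the interaction.

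The 256 called results of 130 named genes kept in the text were recomputed 4996 times over all alternatives. Of these 4349 kept direction and call, 647 direction only and 0 reversed, though the fold change cutoff cannot reverse any. Of 2972 recomputed results not called, 161 were called in the same direction, 133 changed sign without a call and 0 reversed with one. Counts of calls moved more. On the deposited log2(TPM + 1) scale there were 671 calls in the small intestine, 160 for the interaction, 376 between tissues in GFP-positive and 1509 in GFP-negative cells, and with log2(TPM + 0.1) 982, 106, 502 and 1394. With only the libraries compared there were 850 in the small intestine, 3016 in the colon and 406 between tissues in GFP-negative cells. DESeq2 gave 1088 for the interaction and 1390 and 1635 between tissues in GFP-positive and GFP-negative cells, and 862 and 363 calls shared by the GFP effects and by the tissue effects. Limma-voom gave 179 for the interaction and 364 between tissues in GFP-positive cells. Without 1 library the counts ranged from 816 to 1140 in the colon, 69 to 1044 for the interaction, 416 to 613 between tissues in GFP-positive and 187 to 1229 in GFP-negative cells, with 2 libraries left in 1 group and fewer samples in the fit. Apart from fewer samples in a fit, the cause of these shifts was not tested. With the replicate block the counts were 1931, 1535, 330, 853 and 944, of which 1506, 1264, 201, 700 and 658 were also called without it, in the order small intestine, colon, interaction, GFP-positive and GFP-negative. The block also ended the list calls of collagens, complement and retinoid genes in the colon and of R-spondins between tissues in GFP-negative cells. For the interaction it ended that of Wnt antagonists (0.0597). It added the lists of B and plasma cells in the small intestine, neurons in the colon, and lymphatic and all endothelium between tissues in GFP-positive cells. Between tissues in GFP-negative cells it added pericytes, leukocytes and B and plasma cells. No other list call changed.

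Of 40 lists, an estimated correlation left 0 called in the small intestine and 0 in the colon (8 and 9 at an unadjusted p under 0.05), and 1 each for the interaction, GFP-positive and GFP-negative cells, against 20, 26, 25, 16 and 24 with the preset value. Fry called 15 for the interaction and 10 between tissues in GFP-positive cells, and 15 and 23 in the small intestine and colon. Library sizes without factors moved the median of all genes to -0.129 in the small intestine and -0.139 in the colon, and the deposited log2 scale moved it to 0.129 and 0.193 between tissues in GFP-positive and GFP-negative cells. On that scale 51.1% of calls were higher in the small intestine (39.0% in the main test), 30.6% for the interaction (56.5%), and 82.7% (60.3%) and 87.3% (52.3%) between tissues in GFP-positive and GFP-negative cells. Library sizes without factors gave 62.7% in GFP-negative cells. With 3 libraries per group most 2-fold changes are below what these tests recover.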

Other observations

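The values in this part were chosen after the results were seen, and no explanation is tested.

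Cel, a lipase gene of the exocrine pancreas, measured 214, 7.42 and 93.3 CPM in small intestinal GFP-negative replicates 1 to 3, and Ctrb1, a chymotrypsinogen gene of the same tissue, 157, 2.09 and 64.8 CPM. Between colonic and small intestinal GFP-negative cells they were called as lower (-10.03 ± 2.11, adjusted p = 0.0478, and -9.05 ± 1.89, adjusted p = 0.0447). Each call ended in 5 of the 6 fits without a library, with 0.214 without colonic GFP-negative replicate 3 for Cel and 0.223 without colonic GFP-negative replicate 2 for Ctrb1.

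In small intestinal GFP-positive replicates 1 to 3 Rspo3 was even, at 196, 191 and 192 CPM, while Lyve1 measured 1260, 1550 and 422 CPM, Grem1 1030, 538 and 1530 CPM and Ackr4 374, 428 and 571 CPM. In the colonic GFP-positive libraries Lyve1 was 2730, 2640 and 2250 CPM and Grem1 872, 788 and 762 CPM. With 3 libraries per group no correlation was computed.

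Over the 2000 most variable genes the first components of a principal component analysis took 37.6%, 23.4%, 10.6% and 8.33% of the variance. Small intestinal GFP-negative replicate 3, the library with immunoglobulin transcripts, lay at -68.4 on the third.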
